A study of Mus musculus with 3 samples.

How the data were processed

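RNA levels were measured in 3 libraries of mouse RAW264.7 cells: RANKL alone, and RANKL with TSH for 2 h and for 24 h, 1 library each. Per the labels' protocols, the libraries were made from total RNA with a SMARTer mRNA kit. Per the submitters' processing notes, the builds are GRCm38 and mm10, which name the same assembly. The aligner, the counting tool, its handling of strand and of reads with several positions, and the annotation release are not given in the sources used here.

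The values are FPKM (fragments per kilobase of gene length, scaled to depth) as the authors deposited them, with 1 column per library and 54532 genes, and 0 per-sample columns were left unused. The gene length in bases, deposited by the authors beside the values, belongs to no library. The column for RANKL alone was known from its name. The other columns begin with T, and their names leave the hours of TSH open, so comparisons planned as 2 h and 24 h are reported as T1 and T2.

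FPKM times gene length was a whole multiple of a single step in each library, within 0.01 for 100% of values above 0, so reads per gene were recovered. The reads summed to 16156926, 16809034 and 17390744, and the depth that the step implies differed from these sums by -0.177%, -0.241% and 0.763%. A floor of 3 reads in a gene of 1 kb is 0.186, 0.179 and 0.171 FPKM. The reads gave counting intervals only, since PCR copies are not independent molecules.

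Changes were computed as log2 of (FPKM + 1), a scale that understates changes of low genes, for 11069 genes with a mean of at least 1 FPKM. With 1 library per group there was no test. A gene was counted where the absolute log2 change was at least 1. Ratios of FPKM, without the added 1, carry exact conditional (Clopper-Pearson) 95% intervals from the reads. "Beyond counting error" means that this interval left out 1, and it compares those libraries, not the conditions. Well covered genes can pass it at small changes. Of 12 common reference genes, 3 were lower and 2 higher beyond it in T1, and 4 lower and 3 higher in T2, each against RANKL alone.

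Before the data were examined 39 gene lists were fixed, with 561 symbols, of which 560 were found. A symbol with several identifiers was read from the one with the highest mean. For 34 lists with at least 5 members past the filter, the median was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart under percentile 2.5 or over 97.5. This describes these libraries only. The other 5 lists are given gene by gene.

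The genes named were fixed by a rule: per TSH comparison the 10 largest rises and 10 largest falls past the filter and the size rule, and 5 each way for T2 against T1, leaving out predicted, clone, small RNA and pseudogene names, which left fewer than 10. To these were added up to 4 members per list with the largest change, and always Tshr, the AMPK subunit genes, Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp and Calcr. Other genes named were chosen after their values were seen.

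Near-identical copies were sought with BLAST+ 2.17.0 (at least 95% identity over at least 100 bases and 50% of the shorter transcript) among transcripts of GENCODE release M21 on GRCm38, which held 99.8% of the identifiers, 98.1% with the same coordinates. The 50% limit was set after families had been looked at, and 80% was run beside it. Of the genes past the filter 2120 had a copy. Sums over copies are log2 ratios of summed reads scaled to depth, without the added 1, so for low genes they can exceed the gene's own change. Genes with a copy, and genes that overlap others or lie antisense to them, are uncertain.

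For the library of RANKL alone, which both TSH comparisons share, 100 sets of libraries without effect were simulated, with counting noise alone or with normal noise whose variance was taken from the 3 comparisons. How many lists would agree by chance was computed, after the results had been seen, from random lists read in both TSH comparisons. The functions were tested on simulated reads for T1 against RANKL alone. Of the genes changed 2.5-fold and 4.0-fold, among 11074 genes, 85.4% and 100% passed the size rule, and 0% of those changed 1.5-fold did. A list of 21 genes lowered by 0.2 in log2 lay below all random lists, and 5% of 200 unshifted lists stood apart. These reads held counting noise alone and the lists held random genes. This therefore checks the code and does not measure how often real lists stand apart by chance. Alternatives were the pseudocounts 0.1 and 5, no filter, a mean of at least 5 FPKM, libraries rescaled to the same total (the mean of the 3 totals, as in TPM), median-of-ratios scaling, a fold of 1.5 and the mean of members. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.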

Results

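The data were messenger RNA levels in RAW264.7 cells, a mouse macrophage line that forms osteoclasts, the cells that resorb bone, when it is given the cytokine RANKL. Per the labels, the cells received RANKL for 3 days and then no thyroid stimulating hormone (TSH), labelled 0 h, or 10 mU/mL of TSH for 2 h or 24 h. Time in culture may therefore differ along with TSH, and 1 library of RANKL alone cannot separate them. There was 1 library per group, 3 in all, and the labels name osteoclast differentiation and the AMPK pathway as the subject. The deposited table gave 1 column for RANKL alone and 2 columns for TSH, named T1 and T2. Those names do not say which TSH library is that of 2 h and which that of 24 h, so they are called the T1 library and the T2 library here and nothing is read from the hours. Reads per gene recovered from the table summed to 16156926 for RANKL alone, 16809034 for T1 and 17390744 for T2. With 1 library per group no difference has a replicate check, no p-value is given, and the intervals beside ratios cover counting error only.

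The first question was whether the cells carried the transcripts of osteoclasts. Ctsk, encoding the bone matrix protease cathepsin K, stood at 1336 FPKM with RANKL alone, and Acp5, encoding tartrate-resistant acid phosphatase, at 972 FPKM. Mmp9 was at 199 FPKM, the master regulator Nfatc1 at 165 FPKM and the fusion receptor gene Dcstamp at 83.6 FPKM. Calcr, the calcitonin receptor gene, was low, at 0.697 FPKM from 44 reads. Tshr, the gene of the TSH receptor, had 0 reads with RANKL alone, 2 in T1 and 0 in T2, so its level was not measurable at this depth. Of the lists of other cell types, 0 of 13 osteoblast and fibroblast markers and 0 of 10 neutrophil markers had a mean of at least 1 FPKM. The same limit was passed by 1 of 12 lymphocyte markers, Lck, at 1.25 FPKM with RANKL alone, and by 2 of 11 dendritic cell markers, Cd74 and Itgax, at 89.7 and 1.32 FPKM.

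The T1 library was compared with RANKL alone to ask what differed after TSH. Genes of osteoclast differentiation and resorption were lower in T1: 17 of 21 measured members were lower, 14 of them beyond counting error, and 4 were higher, all beyond it (Car2, Jdp2, Mitf and Nfatc1). Their median log2 change was -0.16, below all 10000 random lists matched on expression, whose central range ran from -0.05 to 0.06. Ctsk (chromosome 3, 95499256 to 95509362, GRCm38) was at 983 FPKM, a ratio of 0.736 (95% counting interval 0.724 to 0.748). Oscar, encoding an immunoglobulin-like osteoclast receptor, had a ratio of 0.760 (0.682 to 0.847), and Clcn7, the lysosomal chloride transporter gene, one of 0.829 (0.793 to 0.867). Nfatc1 was higher, at a ratio of 1.05 (1.03 to 1.07), while Dcstamp, at 0.960 (0.916 to 1.01), did not differ beyond counting error.

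Genes of acid secretion and of the lysosome were lower in T1 as well. The V-ATPase subunits, which build the proton pump, had a median of -0.18 with 15 of 16 members lower, including Atp6v1a at -0.26 and Atp6v0d2 at -0.24. Lysosomal proteins had a median of -0.14 with 15 of 17 lower, among them Hexa at -0.28 and Ctsb at -0.27. In cholesterol biosynthesis all 17 members were lower, 13 of them beyond counting error, with a median of -0.18, and Cyp51 and Sqle were at -0.29 and -0.26. The medians of these 3 lists lay below all random lists. The list of coupling factors was meant to hold signals from osteoclasts to bone-forming cells. Its 6 measured members had a median of -0.25, at percentile 0.01, with Ctsk at -0.44, Lif at -0.43 and Cxcl16 at -0.33. Ctsk encodes a matrix protease, so its fall is not read as that of a signal. Ctsk is also in the osteoclast list, and Atp6v0d2 is in both that list and the V-ATPase list. These lists are therefore not fully separate results.

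Proliferation genes were higher in T1. All 19 genes of G2 and M phase were higher, 12 of them beyond counting error, with a median of 0.11, above all random lists, and with Bub1 at 0.23 and Kif20a at 0.22. All 17 genes of S phase were higher, with a median of 0.09 at percentile 99.9, led by Tyms at 0.31. Mitochondrially encoded mRNAs had a median of 0.15 at percentile 99.99, and 9 of the 13 share sequence with a copy elsewhere. Ribosomal protein genes had a median of 0.10 at percentile 99.7, but 16 of 20 have a near-identical copy, and the mean of members did not stand apart. Further lists stood apart on the lower side: p53 targets at -0.13, with Trp53inp1 at -0.47, fatty acid oxidation at -0.11, the unfolded protein and integrated stress response at -0.10 and autophagy at -0.09. In all, 13 of 34 lists stood apart in T1, where 1.7 would if all were random lists. Some real lists share members and their genes can vary together, so the number by chance is not known for them.

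Few single genes passed the size rule in T1. Of 11069 genes with a mean of at least 1 FPKM, 115 passed the 2-fold size rule, 63 higher and 52 lower, and 70 of these were small RNAs and 21 pseudogenes. Only 21 had at least 100 reads over the libraries, and 18 of those have a near-identical copy. Among the genes the naming rule picked, Srp54b, encoding a signal recognition particle subunit, was at 0.591 FPKM with RANKL alone and 5.50 in T1, mt-Nd4l at 37.8 and 170 FPKM, mt-Atp6 at 75.8 and 281, Rps27rt at 270 and 1040, and Tuba1a at 5.74 and 16.2. The rest of the higher genes were mt-Co3 at 1.28, Hist1h3i at 1.25 from 1 and 12 reads, and mt-Nd3 at 6.59 and 14.2 FPKM. Rpl17 was lower at -1.57, while the sum over Rpl17 and its copies was higher at 0.16, so its own change is uncertain. Sums over copies were 0.41 for Rps27rt, 0.26 for Hist1h3i, 0.24 for Tuba1a and 0.13 for mt-Nd3, but 1.64 for mt-Nd4l, 1.45 for mt-Atp6, 1.06 for mt-Co3 and 0.91 for Srp54b. Mt3 (chromosome 8, 94152607 to 94154146), a metallothionein gene without such a copy, was at 15.3 FPKM with RANKL alone and 6.55 in T1, a ratio of 0.428 (0.341 to 0.534).

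The T2 library was compared with the same library of RANKL alone. Osteoclast genes were again lower, with 20 of 21 members lower, 19 of them beyond counting error, and a median of -0.21, below all random lists. Ctsk was at 980 FPKM, a ratio of 0.733 (0.721 to 0.745), Acp5 at 0.845 (0.832 to 0.859), Mmp9 at 0.866 (0.844 to 0.890) and Oscar at 0.748 (0.672 to 0.832). Mmp14 was at -0.31, and Calcr was at 0.321 FPKM, a ratio of 0.460 (0.263 to 0.784). Nfatc1 was lower here, at a ratio of 0.961 (0.943 to 0.980).

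V-ATPase subunits had a median of -0.14 in T2, with 15 of 16 lower, and cholesterol biosynthesis one of -0.18, with 17 of 17 lower and 15 beyond counting error, led by Insig1 at -0.30 and Msmo1 at -0.27. Both lay below all random lists. Lysosomal proteins were at -0.11 (percentile 0.130) and the coupling factors at -0.20, below percentile 2.5. G2 and M phase genes were higher, with 18 of 19 higher, 15 beyond counting error, a median of 0.14 above all random lists, and Aurkb, a mitotic kinase gene, at 0.41. S phase genes stood at 0.05, but not apart with the mean of members, and mitochondrially encoded mRNAs at 0.10. Ribosomal protein genes, at 0.04, no longer stood apart with the mean of members. Interferon-stimulated genes were higher at 0.18, with 7 of 9 higher, 2 of them beyond counting error, including Oas2, an antiviral oligoadenylate synthetase gene, at a ratio of 1.81 (1.46 to 2.24). The mean of that list's members did not stand apart.

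Amino acid transport and synthesis genes stood at 0.10 in T2, with 9 of 11 higher, 7 of them beyond counting error, including Cth at 0.25 and Phgdh at 0.16. On the lower side stood the inflammatory cytokines and NF-kB targets at -0.10, LXR and PPARG targets at -0.10, fatty acid synthesis at -0.10, cell fusion at -0.09 and nuclear-encoded oxidative phosphorylation at -0.07. Each of these last 5 lists lost that standing with the mean of members, and the inflammatory list was at 0.0286 with a mean of at least 5 FPKM. Together 16 of 34 lists stood apart in T2, and 9 stood apart in the same direction in both TSH libraries, 5 lower and 4 higher. Random lists read in both comparisons would give 0.345, but their genes do not vary together as those of a real list can, and some real lists share members. Part of this agreement may therefore come from the shared library of RANKL alone.

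By the size rule, 85 genes differed in T2, 50 higher and 35 lower, and 75 of them had under 100 reads. The naming rule gave Srp54b at 1.74, mt-Tw at 1.14 from 4 and 11 reads, and Stfa2l1 at 1.13 from 6 and 23 reads on the higher side. On the lower side it gave Mt3 at -1.02, the antisense transcript Hotairm1 at -1.05 and mt-Ti, with 3 reads in RANKL alone and 0 in T2. Sums over copies were 0.88 for Srp54b, 1.40 for Stfa2l1 and -1.68 for Hotairm1. In both TSH libraries 16 genes were higher and 18 lower by the rule, a balance that changed with the pseudocount and the filter, against 0.285 and 0.164 for independent lists. Simulated libraries without effect gave 0.640 and 0.680 when all spread was normal noise, and 10.2 and 6.02 from counting noise alone. The normal noise gave fewer than counting noise alone, so it understates the overlap of thinly covered genes. The observed 16 and 18 can therefore not be judged against it. The covariance of both sets of changes was 0.0293, against 0.0139 from counting noise alone, while the normal noise was set from these same changes and returns 0.0292 by construction. Their correlation across genes was 0.568, against 0.514 from counting noise alone with the shared library. The 1 library of RANKL alone cannot be split, so part of the overlap may come from it.

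**Figure D1:**
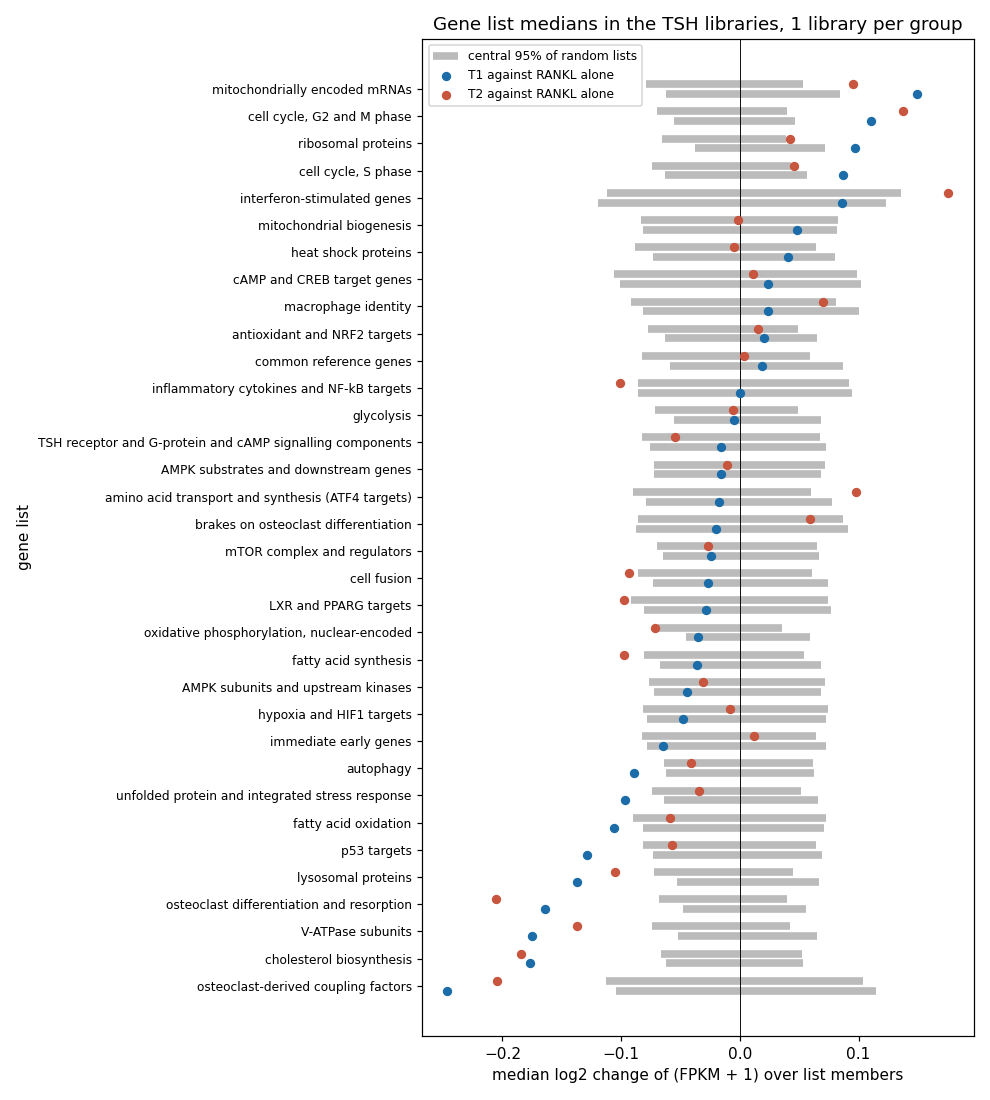
Median log2 change of (FPKM + 1) over the members of each of 34 gene lists in the T1 and T2 libraries against RANKL alone, 1 library per group, with grey bars for the central 95% of 10000 random lists. Osteoclast genes lay at -0.16 and -0.21 and G2 and M phase genes at 0.11 and 0.14, outside their bars.

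The T2 library was compared with T1 to ask how the TSH libraries differed from each other, without the library of RANKL alone. The unfolded protein and integrated stress response list had a median of 0.10, above all random lists, but its members went both ways, with 10 of 16 higher and 6 lower, 6 and 4 of them beyond counting error. Trib3, a pseudokinase gene induced by ATF4, was at 0.68 and Sesn2 at 0.31, while the chaperone genes Hspa5 and Hsp90b1 were at -0.07 and -0.09 and Creld2 at -0.20. Hypoxia and HIF1 targets stood at 0.09, with 10 of 12 members higher and Kdm3a at 0.25. Immediate early genes were at 0.09, with 8 of 15 higher and 7 lower, 4 and 3 of them beyond counting error, Ier3 at 0.39 and Fos at -0.19. Inflammatory cytokines and NF-kB targets stood at 0.09, with 8 of 11 higher, but 1 higher and 2 lower beyond counting error, although the same list had a median of -0.10 in T2 against RANKL alone. On the higher side p53 targets stood at 0.06, amino acid transport and synthesis at 0.05, autophagy at 0.05, antioxidant and NRF2 targets at 0.03 and V-ATPase subunits at 0.02. Random lists for the last 2 lay mostly below 0, with central ranges from -0.064 to 0.030 and from -0.063 to 0.015. With trends with GC content and transcript length removed, neither of those 2 lists stood apart (percentiles 96.0 and 95.4). Mitochondrial biogenesis had a median of -0.09 with 7 of 11 lower and 0 beyond counting error. Mitochondrially encoded mRNAs were at -0.07 with 11 of 13 lower, and S phase at -0.06 with 14 of 17 lower, 6 of each beyond counting error. Of these 12 lists, 2 stood apart with the mean of members, the stress response list and the mitochondrially encoded mRNAs. In the latter 9 of 13 members share sequence with a copy, among them mt-Atp6 and mt-Nd4l, whose large falls weigh on the mean. Without copied genes fewer than 5 members remained, so that list was not read without them.

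Osteoclast genes had a median of -0.05 in T2 against T1, at percentile 3.81, with 17 of 21 lower, 8 of them beyond counting error, and 4 higher, 2 of them beyond it. Without copied genes and those with under 100 reads in the background, the list stood apart at percentile 1.91. With trends with GC content and transcript length removed, it was at -0.034, at percentile 9.4, and did not stand apart. Ctsk was at a ratio of 0.997. By the size rule 92 genes differed, 56 higher and 36 lower in T2, and 82 had under 100 reads. The naming rule gave Rpl17 at 1.39 on the higher side, and mt-Ti at -2.16, mt-Atp6 at -1.40, Rps27rt at -1.32 and mt-Nd4l at -1.24 on the lower side. Sums over copies were -0.05 for Rpl17, -1.05 for mt-Atp6, -0.04 for Rps27rt and -0.88 for mt-Nd4l. Across genes, which are not replicates, Pearson's r of log2 values was 0.990 for T1 with RANKL alone, 0.991 for T2 with RANKL alone and 0.992 for T2 with T1. Spearman's rho was 0.990, 0.990 and 0.991.

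The labels name AMPK, the kinase that senses low cellular energy, so its genes were read in all libraries. Prkaa1, the gene of the catalytic subunit alpha 1, was at 12.8 FPKM with RANKL alone, 13.4 in T1 and 14.0 in T2, while Prkaa2 had 0 reads in each. Prkab1 was at 13.8, 13.3 and 11.6 FPKM, with a ratio in T2 of 0.839 (0.752 to 0.937). Prkab2 was at 3.01, 3.39 and 3.25 FPKM, Prkag1 at 6.21, 5.15 and 6.06, and Prkag2 at 5.65, 5.26 and 5.60, none of them beyond counting error against RANKL alone, and Prkag3 had 1 read in T2 alone. The list of AMPK subunits and upstream kinases had medians of -0.04 in T1 and -0.03 in T2, at percentiles 12.2 and 20.8. AMPK substrates and downstream genes were at -0.02 and -0.01, and mTOR complex genes at -0.02 and -0.03, all within the range of random lists. Sesn2, a stress-induced regulator upstream of AMPK, had a ratio of 0.733 (0.657 to 0.817) in T1 and 0.924 (0.835 to 1.02) in T2. mRNA levels do not measure the activity of a kinase.

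**Figure D2:**
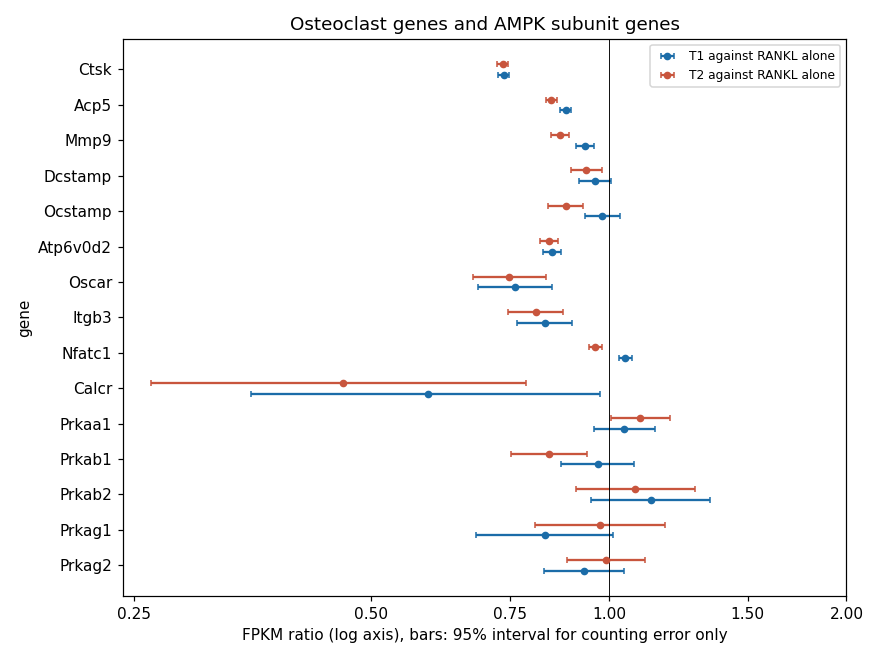
Ratio of FPKM in T1 and T2 to RANKL alone, on a log axis, for 10 osteoclast genes and 5 AMPK subunit genes, 1 library per group, with bars for the 95% counting interval. Ctsk lay at 0.736 and 0.733, and Prkaa1 at 1.05 and 1.10.

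The list of TSH receptor and cAMP signalling genes gave medians of -0.02 in T1 and -0.05 in T2. These rest on 13 of 16 members and leave out Tshr, which did not pass the filter. The cAMP and CREB target genes gave 0.02 and 0.01, and all 4 medians were inside the range of random lists. Nr4a1 and Nr4a2, nuclear receptor genes that cAMP induces, were at -0.20 and 0.05 in T1 and at -0.08 and 0.16 in T2. Immediate early genes were at -0.06 and 0.01 against RANKL alone, with Jun at -0.36 and -0.47. Further lists inside that range in both were brakes on osteoclast differentiation (-0.02 and 0.06), macrophage identity (0.02 and 0.07, the latter at percentile 98.8 without copied genes), glycolysis (0.00 and -0.01), heat shock proteins (0.04 and -0.01), hypoxia targets (-0.05 and -0.01), antioxidant targets (0.02 and 0.02), mitochondrial biogenesis (0.05 and 0.00) and reference genes (0.02 and 0.00). Replication-dependent histones had 3 members past the filter, Hist1h1c at -0.19 and -0.15, Hist1h2bc at -0.10 and -0.08 and Hist1h2bg at -0.03 and -0.47.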

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

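The tests of copies, of a common factor over osteoclast genes and of the RANKL library were chosen after the results had been seen.

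Nfatc1 went opposite ways in the TSH libraries, at 0.07 in T1 and -0.06 in T2 against RANKL alone, a difference of -0.12 in log2. Trib3 was at -0.33 in T1 and 0.35 in T2, a difference of 0.68. In each case both counting intervals left out a ratio of 1, and neither difference between libraries could be tested against replicates. Over 8078 protein-coding genes with at least 100 reads and no near-identical copy, the median absolute deviation of log2 changes was 0.069 in T1 and 0.072 in T2. The changes of Nfatc1 were of about that size, so they do not set it apart from other genes.

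The 2-fold differences in T1 fell into thinly and well covered genes. Counting noise alone gave a mean of 50.4 such genes with under 100 reads in 100 simulated draws, and 73 at most, against 94 observed. No draw reached the observed number, so counting noise as simulated did not account for all of them. The share that it accounts for stays open. For genes with at least 100 reads it gave 0.07 against 21 observed, which argues against counting noise as their cause. Reads divided differently among near-identical copies remain a candidate explanation: for 14 of the 18 with a copy the change summed over the family was under 0.5 in log2, with the 50% and the 80% coverage limit alike, short of the share set for calling it the cause. The exceptions were mt-Nd4l, mt-Atp6, mt-Co3 and Srp54b, and a response to TSH was not separately tested. The count of 14 cannot decide this, since a gene with far fewer reads than its copies barely moves the sum, whatever changed it. The 14 are also not separate, as Rpl17 and Rpl17-ps10 had the same sum, 0.159.

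Osteoclast genes were lower in both TSH libraries. A trend with GC content or transcript length was argued against, since the T1 median was -0.16 before and after its removal, and the T2 median was -0.19 after it, both below all random lists. Whether a lower share of osteoclasts, each with the same RNA, accounts for it stays open. The changes of 9 restricted genes in T1 ran from -0.44 to -0.03. Their SD was 0.14, above their counting error of 0.0367, so 1 common factor with counting error alone is too little. In T2 against RANKL alone the SD over the 9 genes was 0.114. Another 4 members of the list were higher in T1, and in T2 1 was, not beyond counting error. A lower share predicts a fall of restricted genes only, so these members do not bear on it. But the noise of the RANKL library for the 9 genes is not known, and their SD was 0.0477 in T2 against T1, which leaves that library out. A difference of the single RANKL library that is not due to TSH cannot be told apart from an effect of TSH, because both comparisons use it, and the comparison without it, T2 against T1, had a median of -0.05. An effect of TSH stays open as well, untested by replicates.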

How the results depend on the processing

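The protein-coding subsets and the GC and length correction were chosen after seeing the data. Against 115, 85, 92 and 34 genes past the size rule (T1, T2, T2 against T1, both TSH comparisons), the counts were 219, 197, 176 and 88 with a pseudocount of 0.1, and 17, 8, 13 and 2 with one of 5. They were 223, 208, 201 and 82 without a filter, 25, 13, 16 and 5 with a mean of at least 5 FPKM, and 290, 272, 251 and 125 at a fold of 1.5. In protein-coding genes with at least 100 reads they were 13, 3, 6 and 3, and without near-identical copies 2, 1, 1 and 1. Stricter limits test fewer genes, and low genes weigh more with a small pseudocount. Both rescalings kept all 4 counts within 1.5 times. The share of higher genes in T2 was 58.8%, but 12.5% of 8 genes with a pseudocount of 5 and 30.8% of 13 with a mean of at least 5 FPKM, where that in T1 was 44.0% against 54.8%. In protein-coding genes with at least 100 reads it was 33.3% of 3 in T2 and 33.3% of 6 in T2 against T1. In both TSH comparisons 16 genes were higher and 18 lower, but 57 and 31 with a pseudocount of 0.1, 0 and 2 with one of 5, 24 and 58 without a filter, 0 and 5 with a mean of at least 5 FPKM, and 76 and 49 at a fold of 1.5. With the mean of members 8 lists stood apart in T2 and 2 in T2 against T1, and the cause was not tested. Of 906 list values, 841 kept their side of the limits, 52 no longer stood apart, 12 newly did and 1 reversed: inflammatory cytokines and NF-kB targets in T2 were at 0.0286 with a mean of at least 5 FPKM. Without copied genes macrophage identity in T2 and brakes on osteoclast differentiation in T2 against T1 newly stood apart, at 0.0702 and 0.114. The osteoclast list came to stand apart in T2 against T1 without copied genes, at -0.0525. From percentile 97.35, just inside the limit, the AMPK subunit list did so with the same total (0.093). It also did with a mean of at least 5 FPKM (0.0613) and without copied genes (0.0613), and the cause was not tested. Pearson's r was 0.980, 0.982 and 0.984 with a pseudocount of 0.1, and 0.993, 0.995 and 0.995 with a mean of at least 5 FPKM. Of 3108 values of named genes 29 moved beyond their counting interval and none past the size rule changed sign. Depth limits genes near 1 FPKM: of 192 genes past the size rule in any comparison, 165 had under 100 reads.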

Other observations

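These genes were picked after their values were seen, from those without copies and with at least 1000 reads that moved most in the same direction in both TSH libraries, so their shared direction is a result of the choice and rests in part on the shared library of RANKL alone. Lower in T1 and T2 were Ckb, the brain-type creatine kinase gene abundant in osteoclasts, at ratios of 0.708 (0.694 to 0.723) and 0.715 (0.701 to 0.729), and Gpnmb, a glycoprotein gene, at 0.762 and 0.754. Cd109 stood at 0.759 and 0.773, the TGF-beta receptor gene Tgfbr1 at 0.780 and 0.719, and Il1rn, encoding the interleukin 1 receptor antagonist, at 0.689 and 0.742. Higher were Oas3, an antiviral gene, at 1.40 (1.24 to 1.58) and 1.63 (1.45 to 1.83), Lgals3bp at 1.23 and 1.30, and the histone methyltransferase gene Suv39h1 at 1.27 and 1.24.

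Neighbouring metallothionein genes on chromosome 8, which encode metal-binding proteins, went opposite ways. Mt1 was at 409 FPKM with RANKL alone, 475 in T1 and 526 in T2, while Mt3 was at 15.3, 6.55 and 7.01 FPKM, and Mt2 at 9.28, 4.67 and 5.73 FPKM from 88, 46 and 59 reads. Ppia, often used as a reference gene, was at 194, 366 and 378 FPKM, while the sum over it and its copies was higher by 0.28 and 0.29 in log2.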
